A study of Arabidopsis thaliana with 2 samples.

How the data were processed

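RNA of rosette leaves from 2-week-old *Arabidopsis thaliana* plants, grown in 16 h light and 8 h dark, was measured on 2 arrays of 2 colours. Each array carried 1 plant that over-expressed NST1, a NAC transcription factor of secondary wall thickening, in Cy5 and wild type in Cy3, per the labels. The over-expressors were the independent transformants no. 36 and no. 44, called plant 36 and plant 44. No array had the dyes swapped, so a dye effect on a gene cannot be separated from the genotype. As far as the labels tell, wild type was 1 control sample, and each ratio was tested against 0, which leaves out the spread of wild type itself. The p-values measure the spread between the 2 over-expressor plants alone.

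The values were the authors' deposited log ratios, 1 per probe and array, for 22575 probes with no missing value. How the authors made these deposited values, which were read here as log10 ratios, is not given in the sources used here beyond the dyes and RNA, per the labels. They were read as log10 because they were held within -2 and 2, a limit reached on plant 44 by 9 probes at the lower and 1 probe at the upper end, and because array software of this kind writes log10 of Cy5 over Cy3. The log base, the centring and the direction of the deposited ratio are not given in the sources used here. A positive value is likely higher in the over-expressor, from the dye labels and the sample titles, and NST1 was not among the probes with a name here, so the direction could not be checked on it. The median over all probes was -0.002 on the array of plant 36 and -0.004 on that of plant 44. Folds are given as they follow if the base is 10. Scanner intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

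Probes were named through a table of the platform's annotation, with symbols updated through the gene identifiers of the TAIR10.1 RefSeq table. Of the probes, 9335 had 1 gene, 40 had several and 13200 were unnamed here. Of the 9335, 9317 matched the RefSeq table and 18 kept the older name. They stood for 9253 genes, 79 of them with more than 1 probe. The naming was checked in a pair of ways. The log ratios of the 2 probes of 77 genes correlated across genes with Pearson r = 0.235 (permutation p = 0.0372, 10000 permutations) and Spearman rho = 0.366 (permutation p = 0.0012), and 45 of the 77 pairs had the same sign. In 0 of the 77 genes did both probes pass the test described here, and in 13 only 1 did. The highest r of 1000 draws of random probe pairs was 0.424, so this check bears out the naming weakly at best. Genes are not independent replicates, and these genes varied less than others, with an SD of 0.105 against 0.168 among other probes with 1 gene. In the other check, the median of 147 probes of cytosolic ribosomal protein genes was -0.29 at the listed probe numbers and between -0.02 and 0.00 at numbers 1 to 3 places before or after. This list was written after some of its low members had been seen under the same naming. The 137 probes of members not looked at before, as defined further on, had a median of -0.28 at the listed numbers.

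Each probe was fitted with limma 3.58.1 in R 4.3.3, with an intercept only and empirical Bayes moderation (1 residual degree of freedom and a prior of 1.37), two-sided against 0. The Benjamini-Hochberg adjustment ran over all 22575 probes, with a threshold of 0.05. "Rose" and "fell" are used of probes past this threshold. The values were not centred again. Counts of probes at or beyond 2-fold (0.30 on the log10 scale) on both arrays were given without a test. Probes of 1 gene were averaged for its value, and such a gene counted as changed if all its probes passed with 1 sign. Errors are the SD of the 2 plants.

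Before the data were examined, 21 gene lists with 313 loci were fixed, of which 45 loci were measured, meaning that a named probe stood for them. A rule for ribosomal proteins by gene description matched 0 genes. The 11 lists with at least 2 measured probes were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 11. The rule for named genes was also fixed then. It took NST1, up to 4 members of each list with the largest mean among those past the threshold (the 2 with the largest mean where none passed), the 10 genes with the highest and the 10 with the lowest mean among those past the threshold, and the 5 genes with the largest difference between the plants in each direction. LHCB4.1, PSBW, RCA and COR15A are named outside that rule, as are the genes of the closing observations.

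The tests were checked on simulated data. Of 4800 probes changed 2-fold among 22575, 86.6% were recovered, with 215 false calls. With wild-type RNA shared by both arrays and varying like a plant, 86.1% were recovered with 591 false calls, a share of 12.5% of the calls. With only 50 probes changed at each of 4 sizes from 1.5-fold to 8-fold, 0% passed at the adjusted threshold. In camera, 9 of 200 unshifted lists had an unadjusted p under 0.05. The simulated probes were independent of each other, so this check cannot show how camera behaves with genes that vary together.

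The alternatives were centring, scaling between arrays, a robust prior, no prior, probes at 0 or of opposite sign left out, a threshold of 0.01, a minimum fold of 1.2, other size limits, single arrays, averaged probes, an estimated correlation, ranks and random lists. Others, chosen after the data were seen, were a fit on probes with 1 gene, leaving out 462 unnamed probes that lay below -1.2 on both arrays, leaving out 73 probes that held the same pair of values, a log2 reading and percentile limits. The 462 probes had medians of -1.55 and -1.66, and 292 of their 461 spacings were 7 or 8 probe numbers. Whether they are control spots is not known here, and they stayed in the main fit. For the closing observations, 6 more gene lists were written from memory after some values had been seen, and 41 families of at least 5 genes with the same symbol stem were formed. Both were tested with camera among the probes with 1 gene, with the adjustment over the lists of each kind. Members looked at before, defined as the 90 highest and 70 lowest changed named probes, were then left out of 3 of these lists, and camera was adjusted over the 3. The result of 1 of the families and the values of 1 reference gene are not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.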

Results

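Gene expression in rosette leaves of 2 independent *Arabidopsis* plants that over-expressed NST1 was compared with wild type on 1 array each, giving 1 group of 2 plants. NST1 is a NAC transcription factor that switches on secondary wall thickening, and over-expressors form such thickenings outside their usual cells, per the labels. The question was which leaf transcripts differ from wild type in these plants. Values are deposited log ratios, read as log10 and likely as over-expressor over wild type. Base, centring and direction are not given in the sources used here, so folds hold only if the base is 10. NST1 itself was not analysed here, because no named probe stood for it.

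Among the 9335 probes with 1 gene, 933 rose and 1156 fell in the over-expressors (limma, adjusted p threshold 0.05). The highest was the peroxidase PRX52 (AT5G05340), at 1.3 ± 0.11 (SD, n = 2 plants), which is 19.9-fold if the base is 10. Next came AT1G26390, a berberine bridge enzyme-like oxidoreductase, at 1.17 ± 0.20, and AT5G44380, of the same family, at 1.13 ± 0.01. The bHLH factor AT4G28790 lay at 1.13 ± 0.23 and AT2G17740 at 1.13 ± 0.08. The plant defensin PDF1.2 (AT5G44420) rose to 1.09 ± 0.03, or 12.3-fold. The others among the 10 highest were AT5G38900 at 1.05 ± 0.01, AT4G33150, an enzyme of lysine breakdown, at 0.99 ± 0.17, the AP2/ERF factor AT1G36060 at 0.98 ± 0.10, and AT5G47330 at 0.96 ± 0.02. Their adjusted p lay between 0.0168 and 0.037.

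The gene with the lowest mean was AT2G33850, at -1.29 on both arrays, and it was the single named probe below -1.2 on both, a range that also held 462 unnamed probes. AT5G45670, a GDSL-type lipase, lay at -1.05 ± 0.19, or 11.2-fold lower if the base is 10. AT1G11850 lay at -0.89 ± 0.14, AT4G29020 at -0.87 ± 0.07 and AT5G02890 at -0.81 ± 0.15. The subtilase SBT1.3 (AT5G51750) fell to -0.81 ± 0.06 and AT5G17700 to -0.80 ± 0.07. AT1G04660 fell to -0.78 ± 0.02, AT1G23410 to -0.77 ± 0.02 and the GDSL-type lipase AT4G18970 to -0.76 ± 0.17. Their adjusted p lay between 0.0168 and 0.04.

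**Figure D1:**
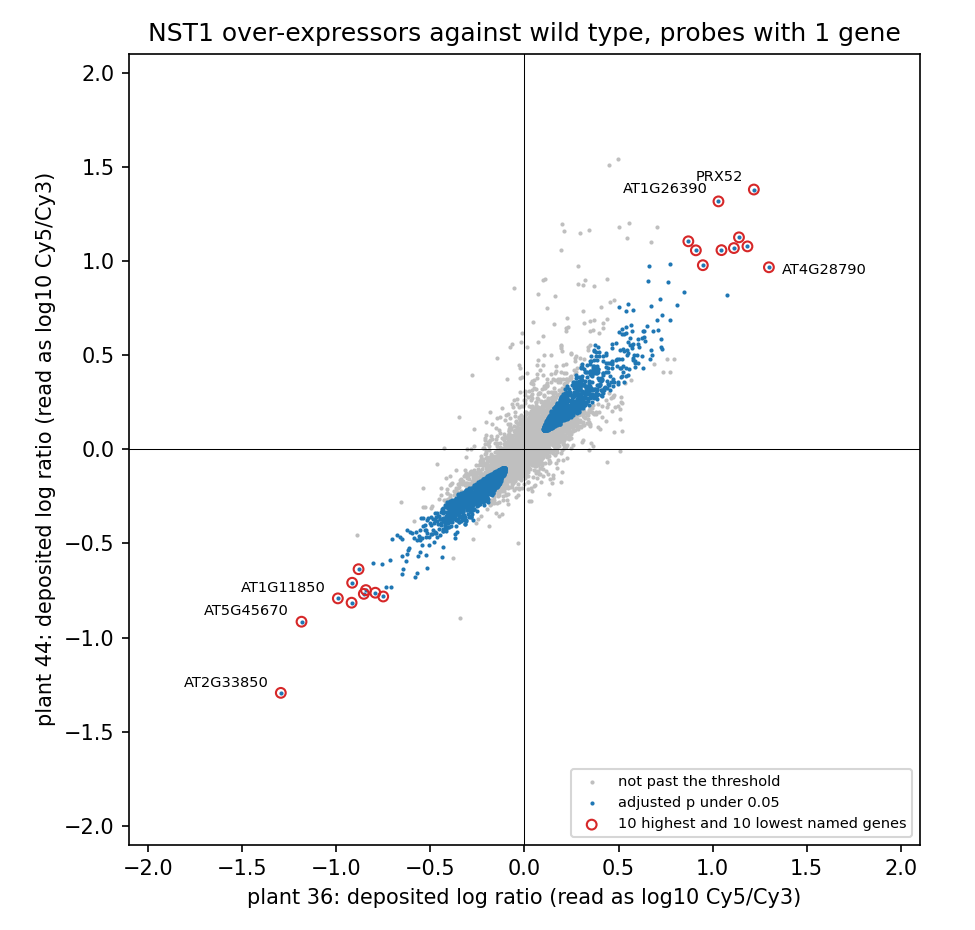
Each point is 1 of 9335 probes with 1 gene. The deposited log ratio (read as log10) is that of plant 36 on the x axis and of plant 44 on the y axis. Blue points passed the adjusted threshold. Red circles are the 10 highest and 10 lowest named genes among those past it, and the 3 most extreme of each are labelled. PRX52 lies at 1.22 and 1.38, and the points follow the diagonal with r = 0.872.

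Of the fixed list of genes linked to lignin polymerisation, 6 were measured, of which 3 rose, 1 fell and 2 did not pass (3 rose and 2 fell adjusted over the list alone). Besides PRX52, PRX71 (AT5G64120) rose to 0.47 ± 0.08 and PRX25 (AT2G41480) to 0.28 ± 0.01, while PRX72 (AT5G66390) fell to -0.22 ± 0.02. The list did not stand apart from other genes (camera adjusted p = 0.584). Both measured genes of vessel cell death rose, the carboxypeptidase SCPL48 (AT3G45010) to 0.45 ± 0.09 and the aspartic protease PASPA3 (AT4G04460) to 0.45 ± 0.07, and both passed adjusted over the list alone (camera adjusted p = 0.197). None of the 3 measured xylan genes passed, over all probes or adjusted over the list alone. The largest values were 0.38 ± 0.18 for IRX15 (AT3G50220), with adjusted p = 0.0931, and 0.06 for the IRX10-L gene (AT5G61840), with camera adjusted p = 0.215 for the list. Neither of the 2 monolignol genes passed by either adjustment, with HCT (AT5G48930) at 0.09 and CCR2 (AT1G80820) at 0.02 (camera adjusted p = 0.447). COB (AT5G60920), the single measured gene of primary wall cellulose, lay at 0.00 and did not pass by either adjustment. The lists of NST and VND regulators, secondary wall transcription factors, secondary wall cellulose, wall patterning, salicylate defence and floral markers had 0 measured members and were not analysed here.

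The 3 measured genes of the fixed list of expansins and XTH, which loosen walls, were all expansins. Of these, EXPA15 (AT2G03090) fell to -0.56 ± 0.14, and the other 2 did not pass (0 rose and 2 fell adjusted over the list alone). The list had camera adjusted p = 0.197. Of 7 photosynthesis genes, the antenna gene LHCB4.3 (AT2G40100) fell to -0.23 ± 0.01, also adjusted over the list alone, and 6 did not pass. The median of that list was -0.15, but LHCB4.1, PSBW and RCA each held the pair of values -0.22 and -0.08 that 73 probes shared. Without such probes the median was -0.05 (camera adjusted p = 0.353, against 0.197 with them).

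In the jasmonate list, PDF1.2 was the single measured gene and rose. In the senescence list, WRKY53 (AT4G23810) rose to 0.24 ± 0.06 and the other of the 2 genes did not pass, whereas both passed adjusted over the list alone (camera adjusted p = 0.211). None of 4 flavonoid genes passed over all probes, but 2 rose and 1 fell adjusted over the list alone. The anthocyanin enzyme DFR (AT5G42800) lay at 0.89 ± 0.30 (adjusted p = 0.0598) and UGT79B1 (AT5G54060) at 0.18 ± 0.04 (adjusted p = 0.0501), with camera adjusted p = 0.584. None of 5 cold, drought and abscisic acid genes passed by either adjustment. COR6.6 (AT5G15970) lay at 0.38 ± 0.15 and COR47 (AT1G20440) at 0.26 ± 0.27 (camera adjusted p = 0.802).

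Among markers of other tissues, the phloem sugar transporter SWEET11 (AT3G48740) rose to 0.32 ± 0.00, the single measured gene of its list, and TRY (AT5G53200), of trichome patterning, lay at -0.02 and did not pass. None of 3 root markers passed by either adjustment, with PYK10 (AT3G09260) at -0.08 and EXPA18 (AT1G62980) at -0.07 (camera adjusted p = 0.215). None of 4 reference genes passed over all probes, while 1 rose and 1 fell adjusted over the list alone. EF1A (AT5G60390) lay at -0.19 ± 0.05 and TIP41 (AT4G34270) at 0.08 ± 0.01 (camera adjusted p = 0.952). No list passed camera, and with an estimated correlation the lowest adjusted p was 0.811. That correlation rests on 1 residual degree of freedom, here and for the lists and families tested later, so results with it decide little either way.

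**Figure D2:**
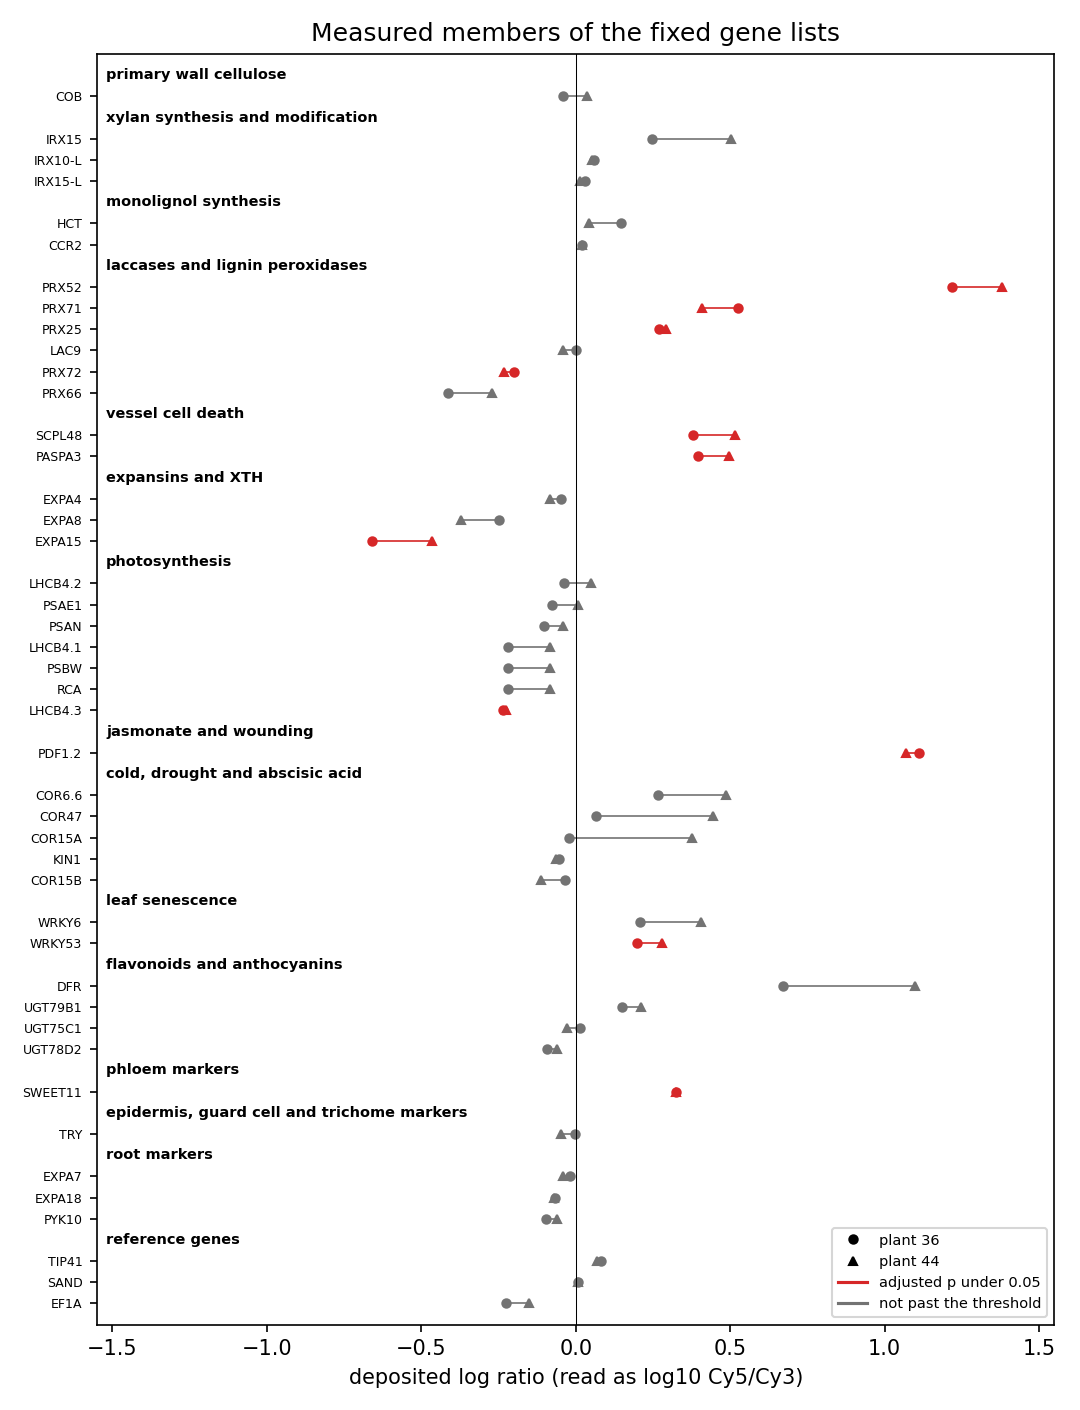
Each line is 1 measured gene of the fixed lists, 3 of the 4 reference genes among them, with the deposited log ratio (read as log10) of plant 36 as a circle and of plant 44 as a triangle; red marks genes past the adjusted threshold. PRX52 and PDF1.2 lie farthest to the right, and COR15A lies at -0.02 in plant 36 and 0.38 in plant 44.

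Over all probes, 2001 rose and 2795 fell, against 1839 and 2164 without the 462 unnamed probes below -1.2, whose nature as genes or control spots is not known here. At or beyond 2-fold on both arrays, if the base is 10, lay 582 of all probes higher and 928 lower, and 466 lower without those 462. Of the probes with 1 gene, 253 lay at or beyond 2-fold higher and 228 at or beyond 2-fold lower on both arrays if the base is 10, and 436 of these 481 passed the test. The median absolute log ratio of the 2089 changed probes with 1 gene was 0.22, or 1.67-fold. The counts changed with the setting. With each array centred on its median, 1431 probes with 1 gene rose and 1441 fell, with centring and scaling 1517 rose and 1485 fell, and at an adjusted p of 0.01 limma called 0. Without a prior, 0 passed, with 4329 of all probes at an unadjusted p under 0.05, against 9718 in limma. In simulations with no probe changed and shared wild-type RNA varying like a plant, limma gave 3276 such probes on average.

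The plants were independent transformants, and their arrays were compared across the 9335 probes with 1 gene, which are not independent replicates. Pearson r was 0.872 and Spearman rho 0.863. The covariance was 0.026, against 0.00382 in 100 simulations of unchanged plants measured against 1 shared wild type, a difference of 0.0221. The simulated r was 0.497 on average. In 83.2% of probes both values had the same sign, against 65.9% in the simulations. Plant 36 had 367 probes at or beyond 2-fold higher and plant 44 had 416, with 253 in both, where independent lists would share 16.4. Lower values numbered 392 and 262, with 228 in both against 11 for independent lists. Part of the excess may come from the shared wild type or from dye effects, since the over-expressor was in Cy5 on both arrays. Neither could be split from the genotype.

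The plants differed by 2-fold or more in 109 of 9253 genes, 89 higher in plant 44 and 20 higher in plant 36, with no test because each plant had 1 array. The largest difference was in AT5G09480, at 0.45 in plant 36 and 1.51 in plant 44. AT5G39520 lay at 0.50 and 1.54, AT2G18370 at 0.2 and 1.2, AT2G38240 at 0.21 and 1.16, and AT3G17520 at -0.05 and 0.86. In the other direction, the calmodulin-like gene CML41 (AT3G50770) lay at -0.34 in plant 36 and -0.90 in plant 44. MSRB5 (AT4G04830), a methionine sulfoxide reductase, lay at 0.51 and -0.01. AT5G47510 lay at 0.44 and -0.07, AT5G56370 at -0.03 and -0.50, and the MADS-box gene AGL19 (AT4G22950) at 0.52 and 0.10.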

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

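The alternatives with only probes of 1 gene, without probes below -1.2, without the shared pair, with a log2 reading, with percentile limits and with the correlation over all probes were chosen after the data were seen. No named gene or list past the threshold changed sign, but the balance of counts and some list medians that had not passed did, as given here. Counts are given for all probes that rose and fell, then for probes with 1 gene. Centring gave 3021 and 1431 that rose, and centring with scaling 3187 and 1517. With scaling, 1485 probes with 1 gene fell, so that the excess of falls in the main counts (933 rose, 1156 fell) became a slight excess of rises. Leaving out probes at 0 gave 3048 and 1437 that rose, and leaving out probes of opposite sign 3576 and 1705 that rose and 1737 with 1 gene that fell. The prior degrees of freedom went from 1.37 to 1.87 with centring and to 2.01 without probes at 0, of which 249 were at 0 on both arrays and so had no spread. A fit on probes with 1 gene gave 1609 that rose and 1620 that fell, and genes averaged gave 1616 that rose. Without the 462 unnamed probes below -1.2 the counts were 1839, 2164, 856 and 1083. A minimum fold of 1.2 gave 694, 1365, 322 and 443. The ordinary test and an adjusted p of 0.01 gave 0 in every count, with 4329 and 9718 probes at an unadjusted p under 0.05.

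At or beyond 3-fold on both arrays lay 203 probes higher and 540 lower, 80 and 34 with 1 gene, and at 1.5-fold 1532 and 2073, 700 and 797. A log2 reading gave 17, 466, 6 and 1, and percentile limits 123, 186, 40 and 0. On single arrays, 809 to 1017 of all probes lay higher and 1006 to 1262 lower, with 1 gene 367 to 416 higher and 262 to 392 lower. Among probes with 1 gene, lower values outnumbered higher ones in plant 36 alone (392 against 367) and at 1.5-fold, unlike at 2-fold on both arrays (228 against 253), whereas over all probes lower values outnumbered higher ones there too (928 against 582), but not without the 462 unnamed probes below -1.2 (466 against 582). Against random lists, 3 lists passed that camera did not, vessel cell death (0.45), expansins and XTH (-0.31) and photosynthesis (-0.15, a median set by the shared pair), each with adjusted p = 0.0491. That test takes genes as independent and leaves out the spread between plants. The vessel and expansin lists held only 2 and 3 probes. Wider families by symbol stem had smaller shifts than the -0.31. The median was -0.07 for 9 EXPA genes (camera adjusted p = 0.309), of which 7 lay below 0 on both arrays and 1 above. For 8 XTH genes it was -0.03 (camera adjusted p = 0.869). The EXPA family includes EXPA7 and EXPA18, listed here as root markers, so it is not a like set and does not decide on the -0.31. On single arrays the flavonoid median was 0.009 to 0.02 and the root median -0.067 to -0.06. The cold, drought and abscisic acid median turned sign, at -0.022 in plant 36 and 0.377 in plant 44, as did that of the reference genes, at 0.015 and -0.0225, and the photosynthesis median was -0.22 and -0.082. Over all probes the plants correlated at 0.948, and at 0.858 without those 462. The cause of these shifts was not tested. Of 63 named genes, 29 no longer passed at 0.01, 28 without a prior and 6 with the minimum fold. AT2G33850, with the same value on both arrays, could not be tested without a prior, so none of the 29 passed there. With centring, scaling, the robust prior, the fit on probes with 1 gene, or probes at 0 or of opposite sign left out, 5 to 8 more passed. Leaving NST1 out of its list was not run, since no named probe stood for it. Counts of calls without 1 replicate were not run either, because that leaves no residual degrees of freedom. Without intensities, signal over background sets no known limit.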

Other observations

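All gene groups here were chosen after values of the main comparison had been seen, and the test of the shared pair after its result was known. The ribosome stood out. Of 147 probes for cytosolic ribosomal protein genes (146 of 224 listed genes), 115 fell, 0 rose and 142 lay below 0 on both arrays. Their median was -0.29, or 1.95-fold lower if the base is 10, at -0.31 in plant 36 and -0.27 in plant 44, and -0.29 after centring and scaling. Camera gave adjusted p = 6.1e-29 over 6 added lists, but adjusted p = 0.437 with an estimated correlation, which rests on 1 residual degree of freedom. All 3 measured probes of DNA replication and cell division genes, of 36 listed genes, also fell. Their median was -0.47 (camera adjusted p = 0.00709, and 0.521 with an estimated correlation). TOPII and PRL, each at -0.47, were among the lowest probes looked at before the list was written. The list was not tested without them, so its p is no independent support.

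Among 41 families of genes sharing a symbol stem, the autophagy genes named ATG had all 8 measured members above 0 on both arrays, of which 4 rose, with a median of 0.18 (camera adjusted p = 0.0152). With an estimated correlation the family did not pass (adjusted p = 0.943). ATG8H (AT3G06420) lay at 0.35 ± 0.01 and ATG8B (AT4G04620) at 0.29 ± 0.00. Apart from ATG3, all measured members were ATG8 genes, so the shift says little of other autophagy genes. The 12 probes of the 26S proteasome had a median of -0.023, an SD of 0.045 among members, and 0 that rose or fell (camera adjusted p = 0.542).

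Explanations for the lower ribosomal values were set against each other. A choice of a few low members seen beforehand is argued against by the members outside the 90 highest and 70 lowest probes looked at before: their median was -0.28, and 105 of 137 fell. For a bias of abundant transcripts, 8 probes of other abundant leaf transcripts, of 70 listed genes, were compared, and their median lay 0.29 above the ribosomal one. It lay 0.27 above on the array of plant 36 (permutation p = 0.00012, two-sided, 100000 permutations) and 0.29 above on that of plant 44 (permutation p = 1e-05, the smallest they can give). The permutations shuffled probes within 1 array. Their p thus takes probes as independent, which ribosomal genes may not be, and holds no spread between plants. With photosynthesis genes added, a set chosen later, 15 probes lay 0.219 above, and 0.273 above without the 3 that held the shared pair of values. The 8 probes had a median of 0.005, with 1 that fell (camera adjusted p = 0.542). The low values were thus not shared by these listed abundant transcripts. Intensities were not used, so whether the 8 probes were as bright as the ribosomal ones is unknown, and a bias by intensity stays open. Dye bias stays open, because 0 arrays had the dyes swapped. The authors' normalization, which is not given in the sources used here, also stays open, and so does a slower growth of the over-expressors, which may lower ribosomal transcripts and was not tested.

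The pair -0.22 and -0.08 was held by 73 probes, while the next most frequent pair other than zeros was held by 7. All 3 named probes with this pair were photosynthesis genes, against 7 such probes among 9335 (one-sided Fisher's exact p = 2.58e-10). These genes had been seen before this test was chosen, so its p restates the observation and does not decide whether both channels were saturated, which stays open. The scanner's saturation marks were not used here, and no biological explanation was tested.

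Of 22 probes of berberine bridge enzyme-like genes, 9 rose and 0 fell, with a median of 0.26 (camera adjusted p = 0.00366, and 0.437 with an estimated correlation). The choice of this family after its highest members had been seen may account for the shift: the 17 members outside the probes looked at before had a median of 0.14 and camera adjusted p = 0.0869. Leaving out the highest members also lowers the rest, so a true shift of the family stays open.

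Of 69 GDSL lipase probes, 16 fell and 3 rose, with a median of -0.0425, and of -0.0393 in the 62 outside the probes looked at before (camera adjusted p = 0.0132), short of the -0.05 set beforehand. With an estimated correlation the adjusted p was 0.437 for the whole list and 0.307 for those 62. Next neighbours among protein-coding genes correlated at r = 0.0473 over 3428 pairs, a value reached by 23 of 10000 permuted orders, whose highest was 0.066. Without pairs that had both genes in an added list, r was 0.0331 over 3399 pairs. The bound set beforehand, beyond every permuted order, was not reached, which by that rule counts against an arrangement along the chromosome. That bound was too strict to decide this, since the highest value grows with the number of orders. At 2 genes on, r was 0.024 (permutation p = 0.0854).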
